A study of Mus musculus with 12 samples.

How the data were processed

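Expression was measured on 12 Illumina mouse bead arrays, 1 per sample, in cells grown from the mouse embryonic stem cell line CCE (strain 129/Sv). Per the labels, embryoid bodies were grown for 4 days, cells positive for Flk1 (the VEGF receptor encoded by Kdr, a marker of vascular progenitors) were sorted, and these were cultured for 4 days more on collagen IV. Culture was at 21% oxygen (normoxia) or at 1.5 to 2% oxygen (hypoxia), each with or without 4 µmol/l L-685.458, an inhibitor of gamma-secretase, the protease that cleaves and so activates Notch receptors. Cells positive for CD31 (encoded by Pecam1) were then sorted for RNA. The sample titles give 4 groups of 3 replicates, numbered 1 to 3 in each group, and the series record calls the replicates biological.

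The deposited non-normalized table holds, for each array, an intensity per probe on a linear scale and a detection p-value, per the file headers. The intensity had already been background-subtracted by the authors' scanner software, as 23.3% of the values are below 0. The deposited detection p-value moves in steps set by 798 negative control probes. BeadStudio is named in the submitters' processing notes, with no version. The authors' processed table holds an intensity for the same probes on a linear scale, floored at 20, with 45.5 to 48% of the values at the floor; above it each array is a near constant multiple (0.993 to 1.18) of its non-normalized signal. The method behind that scaling is not given in the sources used here. The processed table served only as an alternative.

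The non-normalized intensity was used for the comparisons. Background was corrected by limma (version 3.58.1, in R 4.3.3) with the normal-exponential model fitted from the detection p-value, an offset of 16 was added, arrays were quantile normalized and signals were taken as log2. Of 25697 probes, 23978 carry 1 gene symbol in the deposited annotation, 0 carry several and 1719 are not named. Probes with a detection p-value under 0.05 on at least 3 of the 12 arrays, whatever their group, were kept: 14599 probes, 13752 of them with a symbol, for 9879 genes. A gene is represented by its kept probe with the highest mean signal over all arrays. Where the arrays of one group did not detect a gene at all, its fold is given against the lowest signal that the arrays detect, as "at least". Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

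Each probe was fitted with limma as 4 group means over the 12 arrays (8 residual degrees of freedom), with moderated variances and two-sided tests. The comparisons were hypoxia against normoxia without and with the inhibitor, the inhibitor in normoxia and in hypoxia, and the interaction of oxygen and inhibitor. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05; a second count also asks for a fold of at least 1.5. The 30 gene lists (763 entries, 711 distinct genes, 703 entries with a named probe on the array) were tested with camera, which compares a list's genes with all other genes, at a preset correlation of 0.01 and again with an estimated correlation. The p-values of camera were adjusted over the 30 lists. The fry test was run beside it. Counts of list members past the test are given over all probes and, where said, adjusted over the list alone. The lists, the tests, the alternatives and the rule for named genes were set before the data were examined, except where the text says otherwise.

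The genes named are, in each of the 4 comparisons of groups, the 8 largest rises and 8 largest falls among called probes whose 3 values in one group all lie on one side of the 3 in the other (5 and 5 for the interaction, without that condition). To these come a panel of 28 genes of adrenomedullin, Notch, arterial and venous biology, given whether or not they passed, and up to 4 called members of each list described. Any other gene is said to be chosen after its values were seen.

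The replicate numbers were checked for pairing by correlating the deviations of same-numbered arrays from their group means. The 3 correlations were 0.30 to 0.58 for hypoxia without the inhibitor, 0.11 to 0.25 for hypoxia with it and 0.38 to 0.64 for the inhibitor in normoxia, so by the rule used (each over 0.1) the numbers were taken to pair these samples. They were 0.03 to 0.08 for the inhibitor in hypoxia, so the numbers do not pair those. Arrays numbered 1 and 2 in different groups correlated at -0.07 to 0.38, as same-numbered ones did, so it is replicate 3 that the numbers set apart. The labels do not say what a number shares. The main fit has no term for the replicate number, so its p-values are unpaired. The fit with the replicate block takes the number into account and is given beside it.

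The arrays have no read depth; signal over background and the number of arrays limit precision. Each array detected 13085 to 13901 probes, with a mean signal of 522.3 to 628.6. The standard deviation of the log2 difference between replicates 1 and 2 of a group, over probes with a mean log2 signal above 8, was 0.122 to 0.157, against 0.293 to 0.439 between either of them and replicate 3.

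The fit was tested on simulated data with each probe's mean over the 12 arrays, its pooled spread within groups and 200 probes changed by known folds. This spread was the same on every array and independent between probes, while the real arrays differ in noise (array weights 0.222 to 2.13). The simulation therefore does not show how the tests behave with arrays of unequal noise or with genes that vary together. For hypoxia without the inhibitor 11.9% of the 1.5-fold changes, 61.2% of the 2-fold and 81.8% of the 4-fold changes were called, with 11 false calls among 14801 probes. For hypoxia with the inhibitor the shares were 20.9%, 40.3% and 87.9%, for the inhibitor in normoxia 11.9%, 52.2% and 77.3%, for the inhibitor in hypoxia 19.4%, 62.7% and 87.9%, and for the interaction 2.99%, 35.8% and 75.8%. The false calls of these 4 were 6 of 14846, 6 of 14798, 7 of 14791 and 6 of 14802 probes. A second set of simulations took the spread between replicates 1 and 2 and added a shift of replicate 3 shared by the groups. The shares for 1.5-fold, 2-fold and 4-fold changes were then 23.9%, 58.2% and 81.8% for hypoxia without the inhibitor, and 20.9%, 58.2% and 72.7% with it. They were 28.4%, 61.2% and 80.3% for the inhibitor in normoxia, 37.3%, 56.7% and 83.3% in hypoxia, and 7.46%, 35.8% and 83.3% for the interaction. The replicate block then gave 41.8%, 38.8%, 49.3%, 47.8% and 31.3% of the 1.5-fold changes in these 5 comparisons, with 13, 9, 17, 7 and 10 false calls against 9, 0, 1, 2 and 1 without the block. A list of 30 genes raised 1.3-fold gave a camera p of 2.85e-14 in the simulation of hypoxia without the inhibitor, and a list of 30 unchanged genes 0.261.

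The alternatives tried were the replicate number as a block, other filters on detection, no background correction, an offset of 50, cyclic loess or median scaling between arrays, the authors' processed values, 1 probe per gene, array weights, a trended robust variance, fits on the 6 arrays compared, the fry test, and leaving out each array in turn. Added after the data were seen were a fit with replicate 3 as a batch, a fit on replicates 1 and 2 alone, and the effects of the inhibitor and of hypoxia averaged over the other factor. A chip as a random block was not fitted, as no chip is given in the sources used here. No array and no group was left out of the comparisons. Protein, Notch cleavage and adrenomedullin secretion were not analysed here.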

Results

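The data are 12 bead arrays of CD31-positive cells derived from mouse embryonic stem cells, 3 from each of 4 groups. The groups are normoxia, normoxia with the gamma-secretase inhibitor, hypoxia, and hypoxia with the inhibitor. Each array detected 13085 to 13901 of 25697 probes, and 14599 probes were tested. Some probes for transcripts of the endothelium were bright and others dim. The mean log2 signal in normoxia was 12.17 for Pecam1, which encodes the CD31 used for the sort, 10.61 for Cdh5 (VE-cadherin) and 13.22 for Ramp2, a partner of the adrenomedullin receptor. It was 5.55 for Kdr, which encodes the Flk1 of the first sort, where the lowest signal detected on these arrays was 5.11 to 5.21. Signals of different probes do not rank transcripts by abundance, as another kept probe of Pecam1 had 10.68. Pluripotency genes, chosen after their values were seen, had bright probes too. On normoxia 1 and normoxia 3 the signals were 14.2 and 12.98 for Dppa5a, 10.07 and 8.29 for Pou5f1, and 7.02 and 6.17 for the dimmer Tcl1.

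Replicate 3 stood apart from replicates 1 and 2 in every group. The first principal component (27.4% of the variance) parted the replicate 3 arrays, with scores of 16.7 to 28.7, from the others, with scores of -22.6 to 3.8. The second component (24.6%) parted normoxia from hypoxia. In a comparison of replicate 3 with replicates 1 and 2 within groups, added after the data were seen, 1403 probes were higher and 1460 lower in replicate 3 of 14599 (limma). Pluripotency markers were lower there (median log2 difference -1.07, 13 of 19 measured genes fell and 3 rose, camera adjusted p = 0.000247, adjusted p = 0.575 with an estimated correlation). So were haematopoietic markers (median -0.58, 13 of 23 fell and 1 rose, camera adjusted p = 4.48e-07, adjusted p = 0.0794 with an estimated correlation). Endoderm markers were lower as well (median -0.49, 6 of 12 fell, camera adjusted p = 0.0284, adjusted p = 0.541 with an estimated correlation). Glycolysis genes (median -0.35), interferon response genes (median -0.37) and BMP and TGF-beta response genes (median 0.47) each had a camera adjusted p of 0.00252, with 0.541, 0.541 and 0.183 for the estimated correlation. The marker lists for other cells are therefore given beside the comparisons they move with.

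**Figure D1:**
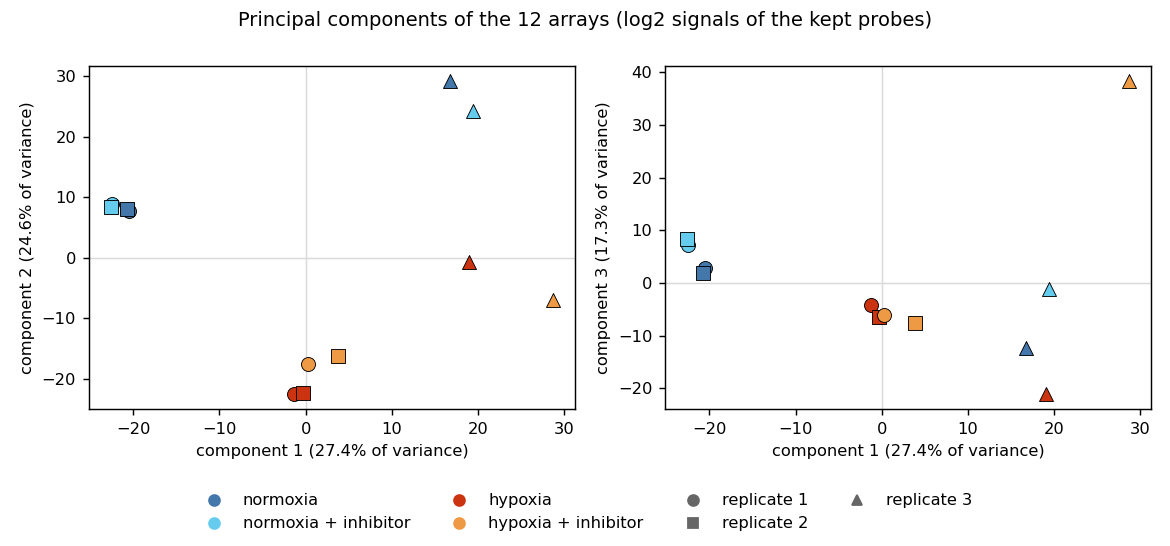
Principal component scores of the 12 arrays from the log2 signals of the kept probes (left, components 1 and 2; right, components 1 and 3), with colour for the group and marker shape for the replicate number. Replicate 3 lies apart from replicates 1 and 2 along component 1, and the hypoxia arrays lie below the normoxia arrays along component 2.

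The first comparison asks what low oxygen alone does to these cells, and in particular whether adrenomedullin, Notch and arterial genes rise. Of the targets of hypoxia-inducible factor (HIF) and the glycolysis genes, those that passed the test were higher in hypoxia in 3 of 3 replicates. Egln3, a prolyl hydroxylase that marks HIF for degradation, rose by 2.15 on the log2 scale (SE 0.12, 4.43-fold, limma adjusted p = 1.62e-05). Adm, which encodes the vasodilator peptide adrenomedullin, rose by 1.75 (SE 0.32, 3.35-fold, adjusted p = 0.0297). The arterial gap junction gene Gja5 (connexin 40) had the largest rise of the named genes detected in both groups, 2.76 (SE 0.54, 6.78-fold, adjusted p = 0.0364, and 0.0438 with the replicate block). The glycolytic enzyme gene Tpi1 rose by 1.65 (SE 0.16, 3.13-fold, adjusted p = 0.000699), while Ak1, an adenylate kinase, fell by 1.33 (SE 0.16, 2.51-fold, adjusted p = 0.0041).

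In all, 91 probes were higher and 57 lower (73 and 48 genes), 140 of the 148 by at least 1.5-fold. With the replicate block the counts were 193 and 126, which include 90 of the 91 and 57 of the 57. Among the largest rises were also those of the lactate exporter gene Slc16a3, undetected in normoxia (at least 4.15-fold), Gpnmb (2.42), the glycogen phosphorylase Pygl (2.40, 5.26-fold), Nrip3 (2.22) and the crystallin gene Cryaa (2.19). The mitochondrial protein gene Mgarp (2.18) and Trf, which encodes the iron carrier transferrin (2.15), followed. Their adjusted p-values were 0.00302 (Pygl) to 0.034 (Nrip3). The largest falls were those of the complement regulator Cd55 (-1.46), the embryonic globin gene Hba-x (-1.45), Mdga2 (-1.40) and Ak1. The guanylate cyclase subunit gene Gucy1b1 (-1.32), Whrn (-1.32), the reductase gene Dcxr (-1.25) and Mreg (-1.23) followed. The adjusted p-values of these genes were 0.00302 (Dcxr) to 0.0255 (Hba-x). For each of these the 3 hypoxia values lay on one side of the 3 normoxia values.

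Of 35 measured HIF targets outside glycolysis 7 rose and 28 did not pass the test. Adjusted over the list alone 20 rose, and 34 of 35 had a positive change (median log2 change 0.69, camera adjusted p = 2.95e-22, adjusted p = 0.00162 with an estimated correlation). Beside Egln3 and Adm they include Fam162a (1.32, adjusted p = 0.0209) and Bhlhe40 (0.96, adjusted p = 0.0394). Vegfa (0.63, SE 0.28, adjusted p = 0.394), which encodes the growth factor VEGF-A, did not pass. Of 17 glycolysis genes 8 rose, 14 when adjusted over the list alone (median 0.93, camera adjusted p = 2.73e-17, adjusted p = 0.0688 with an estimated correlation). The called genes include Slc16a3, Pfkl (2.08, adjusted p = 0.0161), Tpi1 and the lactate dehydrogenase gene Ldha (1.29, adjusted p = 0.0233). With the replicate block 13 HIF targets and 12 glycolysis genes rose over all probes, among them Ak4 (adjusted p = 0.0222, against 0.0643) and Lox (0.0249, against 0.0615), both named here after their values were seen. The glucose transporter gene Slc2a1 (0.30, adjusted p = 0.431) did not pass. Of 41 genes of oxidative phosphorylation none passed, and 38 were slightly lower (median -0.14, camera adjusted p = 6.61e-05, adjusted p = 0.164 with an estimated correlation).

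Of 28 arterial markers 2 rose, Gja5 and Sema3g (1.25, SE 0.25, adjusted p = 0.0401), and 26 did not pass. Adjusted over the list alone 4 rose, as did 4 over all probes with the replicate block (median 0.27, camera adjusted p = 0.0111, adjusted p = 0.334 with an estimated correlation). Most arterial and Notch genes of the panel did not pass, with or without the replicate block. The changes were 1.29 for Nrarp, a target and feedback inhibitor of Notch (SE 0.39, adjusted p = 0.187), and, with adjusted p in brackets, Cxcr4 1.09 (0.416), the Notch ligand gene Dll4 0.38 (0.618), Hey1 0.31 (0.777), Efnb2 0.28 (0.577), Hes1 0.07 (0.958), Notch1 0.15 (0.67) and Gja4 (connexin 37) -0.42 (0.636). Nor did the venous regulator gene Nr2f2 (-0.54, adjusted p = 0.688), Calcrl (0.26, adjusted p = 0.739), which encodes the receptor of adrenomedullin, or Ramp2 (-0.13, adjusted p = 0.884). The rest of the panel did not pass either, with adjusted p of 0.278 (Nrp1) to 0.994 (Ephb4): Ramp3 0.83, Cdh5 0.37, Kdr 0.35, Notch4 0.28, Pecam1 0.27, Sox17 0.27, Nrp2 0.19, Jag2 0.04, Ephb4 -0.01, Nrp1 -0.43, Jag1 -0.49, Hey2 -0.54 and Aplnr -0.60. The Notch target list was not shifted (camera adjusted p = 0.863). Of 23 tip cell genes Adm and Esm1 (1.15) rose, 6 when adjusted over the list alone and 5 over all probes with the replicate block (median 0.28, camera adjusted p = 0.000613, adjusted p = 0.334 with an estimated correlation).

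Of 19 p53 targets Mdm2, the ligase that degrades p53, fell by 0.67 (adjusted p = 0.0394) and 18 did not pass. Adjusted over the list alone 9 fell, and 3 over all probes with the replicate block (median -0.40, camera adjusted p = 4.25e-06, adjusted p = 0.0381 with an estimated correlation). Of 18 genes of cholesterol synthesis and uptake 17 were higher and none passed. Sqle, chosen after its values were seen, rose when adjusted over the list alone (median 0.37, camera adjusted p = 4.25e-06, adjusted p = 0.389 with an estimated correlation). Smaller positive medians were called for 4 lists. For endothelial identity it was 0.10, and of 35 genes Vwf rose, by 1.67 (camera adjusted p = 0.0261, adjusted p = 0.723 with an estimated correlation). The others were S phase genes (0.13, 0 of 24 rose, camera adjusted p = 0.0124, adjusted p = 0.593 with an estimated correlation) and G2 and M phase genes (0.16, 0 of 24 rose, camera adjusted p = 0.00467, adjusted p = 0.566 with an estimated correlation). Interferon response genes had a median of 0.32 (0 of 19 rose, and 1 fell when adjusted over the list alone, camera adjusted p = 0.00621, adjusted p = 0.566 with an estimated correlation). Among 23 haematopoietic markers Hba-x fell and Laptm5 rose by 0.79. Adjusted over the list alone 4 fell and 2 rose, over all probes with the replicate block 4 fell and 3 rose, and the list was not shifted (median 0.00, mean -0.09, test towards a rise, camera adjusted p = 0.709). Pluripotency markers had a median of -0.40 and were not shifted (camera adjusted p = 0.317).

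The number of calls rested on single arrays. It was 38 without normoxia 1, 34 without normoxia 2, 92 without normoxia 3, 25 without hypoxia 1 and 30 without hypoxia 2. It was 337 without hypoxia with inhibitor 3, which is not itself compared but enters the shared variance. Of the 36 named genes called, 8 kept the call whichever of the 6 arrays was left out (Pygl, Cryaa, Ak1, Gucy1b1, Dcxr, Egln3, P4ha2 and Tpi1). The other 28 lost it in some of these fits, with an adjusted p of at most 0.19 (23 without normoxia 1, 26 without normoxia 2, 14 without normoxia 3, 27 without hypoxia 1, 26 without hypoxia 2 and 10 without hypoxia 3). Among them were Adm in all 6 (change 1.54 to 1.87, adjusted p = 0.079 to 0.108) and Gja5 in 5 (2.10 to 3.13, adjusted p up to 0.16). The list calls lost were those of endothelial identity (without normoxia 1, normoxia 2 or hypoxia 3, adjusted p up to 0.501) and S phase (without normoxia 1 or hypoxia 3, up to 0.264). Those of G2 and M phase (without hypoxia 3, 0.0568) and of the interferon response were lost as well (without normoxia 3, hypoxia 1 or hypoxia 2, up to 0.138).

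**Figure D2:**
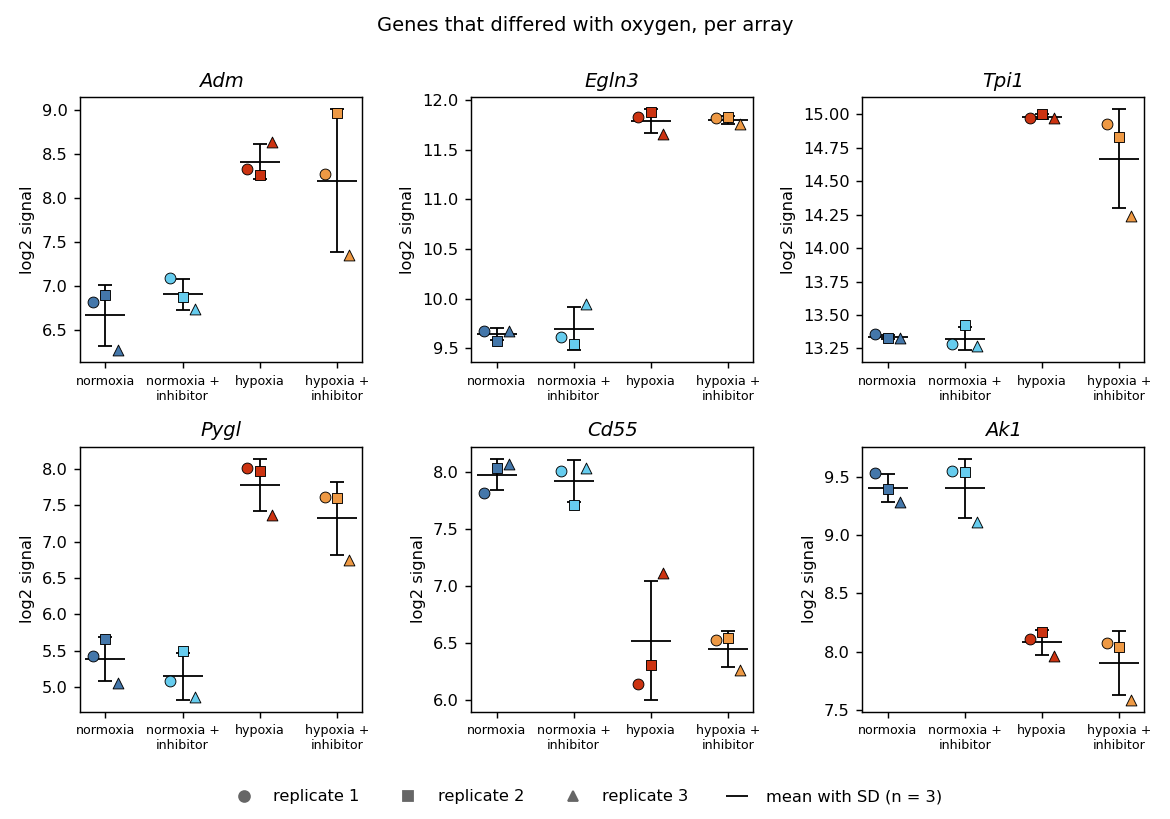
Log2 signal of Adm, Egln3, Tpi1, Pygl, Cd55 and Ak1 on each of the 12 arrays by group, with the mean and standard deviation of the 3 replicates. Adm, Egln3, Tpi1 and Pygl are higher and Cd55 and Ak1 lower in both hypoxia groups, though the change of Adm did not pass the test with the inhibitor.

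The second comparison asks what low oxygen does while gamma-secretase is inhibited. Genes of the hypoxia response and of glycolysis were again among those called. Egln3 rose by 2.11 (SE 0.12, 4.31-fold, limma adjusted p = 1.99e-05), Pygl by 2.17 (adjusted p = 0.00396) and Tpi1 by 1.35 (adjusted p = 0.00322). Ak1 fell by 1.50 (adjusted p = 0.0029). Each did so in 3 of 3 replicates. Adm was 2.45-fold higher in hypoxia and did not pass the test (log2 change 1.29, SE 0.32, adjusted p = 0.105, and 0.0663 with the replicate block), with a change of 0.61 in replicate 3. Gja5 did not pass either (1.44, SE 0.54, adjusted p = 0.306). The largest rise of the genes detected in both groups was that of Gpnmb, a membrane glycoprotein gene (3.09, SE 0.39, 8.49-fold, adjusted p = 0.00416).

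There were 66 higher and 59 lower probes (57 and 53 genes), 117 of the 125 by at least 1.5-fold. With the replicate block there were 139 and 118, including 65 of the 66 and 58 of the 59. Among the largest rises were also those of Cryaa (2.70), Trf (2.33), Pygl, Egln3 and the keratin gene Krt14 (2.06, adjusted p = 0.00363). So were those of the phosphatase gene Dusp26 (at least 3.89-fold, adjusted p = 0.000213) and Slc16a3 (at least 3.02-fold, adjusted p = 0.0386), both undetected in normoxia. After Ak1 the largest falls were those of Cd55 (-1.47), Mreg (-1.37), Mdga2 (-1.30), Whrn (-1.28), Svop (-1.27), the calcium channel subunit gene Cacna2d1 (-1.27, adjusted p = 0.0412) and Dcxr (-1.20). The probes called in both hypoxia comparisons were 41 higher and 35 lower, against 0.411 and 0.23 for independent lists of these sizes. Across 9879 genes, which are not independent replicates, the log2 changes of the comparisons, which share no arrays, had a Pearson r of 0.741 and a Spearman rho of 0.606.

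Of 35 HIF targets 5 rose and 30 did not pass. Adjusted over the list alone 17 rose, and 34 were positive (median 0.55, camera adjusted p = 2.59e-16, adjusted p = 0.00489 with an estimated correlation). They include Egln3, the lysyl oxidase gene Lox (1.69, adjusted p = 0.016), Stc2 (1.38, adjusted p = 0.0449, and 0.0543 with the replicate block) and P4ha2 (0.95, adjusted p = 0.00416), a collagen prolyl hydroxylase. Vegfa (0.83, adjusted p = 0.246), Nrarp (0.96, adjusted p = 0.343) and Slc2a1 (0.36, adjusted p = 0.314) did not pass. With the replicate block 9 HIF targets and 5 glycolysis genes rose over all probes. Of 17 glycolysis genes Slc16a3, Pfkl (1.63, adjusted p = 0.046) and Tpi1 rose, 13 when adjusted over the list alone (median 0.70, camera adjusted p = 3.4e-11, adjusted p = 0.203 with an estimated correlation). Oxidative phosphorylation genes were slightly lower with 0 of 41 past the test (median -0.12, camera adjusted p = 0.00133, adjusted p = 0.332 with an estimated correlation). So were p53 targets with 0 of 19 past it, 4 when adjusted over the list alone (median -0.25, camera adjusted p = 0.00243, adjusted p = 0.203 with an estimated correlation). The arterial list was not shifted (median 0.09, camera adjusted p = 0.319). The rest of the panel did not pass, with adjusted p of 0.225 (Nrp1) to 0.981 (Ephb4). The changes were Ramp3 0.57, Efnb2 0.41, Cdh5 0.41, Sox17 0.33, Notch4 0.28, Nrp2 0.26, Jag2 0.23, Pecam1 0.14, Jag1 0.05, Ephb4 0.02, Hey1 -0.07, Calcrl -0.09, Notch1 -0.10 and Nr2f2 -0.20. Further down were Hes1 -0.23, Hey2 -0.29, Ramp2 -0.32, Kdr -0.34, Aplnr -0.37, Nrp1 -0.48 and Gja4 -0.52. Dll4 was undetected in both groups, and Cxcr4 in normoxia and on 2 of 3 hypoxia arrays.

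Of 23 tip cell genes Rgcc rose (1.02, adjusted p = 0.0318). Adjusted over the list alone 4 rose and 1 fell (median 0.15, camera adjusted p = 0.0158, adjusted p = 0.655 with an estimated correlation). Interferon response genes were higher with 0 of 19 past the test, 3 higher and 1 lower when adjusted over the list alone (median 0.42, camera adjusted p = 0.000237, adjusted p = 0.503 with an estimated correlation). Genes of the unfolded protein and ATF4 response were higher (median 0.42, 1.48 in replicate 3, 0 of 27 rose, 3 when adjusted over the list alone, camera adjusted p = 0.00273, adjusted p = 0.675 with an estimated correlation). So were those of the inflammatory response (median 0.35, 1.00 in replicate 3, 0 of 19 rose, 2 when adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.655 with an estimated correlation). Both calls were lost without hypoxia with inhibitor 3 (camera adjusted p = 0.828 and 0.46), and in replicates 1 and 2 both lists leaned the other way (0.685 and 0.825). Cholesterol genes had a median of 0.18 and -0.36 in replicate 3 (0 of 18 rose, camera adjusted p = 0.026, adjusted p = 0.707 with an estimated correlation). The pluripotency list had no camera call. Of its genes, chosen after their values were seen, Pou5f1, Nanog, Zfp42 and Dppa5a were lower in hypoxia in each replicate, while Klf2 and Klf4 were higher in each.

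The calls numbered 34 without normoxia with inhibitor 1, 36 without normoxia with inhibitor 2, 40 without hypoxia with inhibitor 1, 41 without hypoxia with inhibitor 2 and 255 without hypoxia with inhibitor 3. The tip cell and cholesterol calls were lost without any of the first 4 of these (camera adjusted p up to 0.104 and 0.493). Of the 24 named genes called 12 kept the call whichever of the 6 arrays was left out. The other 12 lost it in some fits, with an adjusted p of at most 0.159 (11 without normoxia with inhibitor 1, 10 without normoxia with inhibitor 2, 6 without normoxia with inhibitor 3, 10 without hypoxia with inhibitor 1, 11 without hypoxia with inhibitor 2, 1 without hypoxia with inhibitor 3).

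The third comparison asks what inhibition of gamma-secretase does at 21% oxygen. The largest difference by p-value was that of Hey1, a repressor gene switched on by Notch. Its mean log2 signal was 8.84 (SD 0.65) without and 6.97 (SD 0.40) with the inhibitor. The difference of -1.87 (SE 0.30, unadjusted p = 4.4e-05) did not pass the test over all probes (limma adjusted p = 0.643). The arterial genes Gja5 (-1.64, SE 0.54, adjusted p = 1) and Gja4 (-1.18, SE 0.29, adjusted p = 1) were also lower in 3 of 3 replicates without passing. Dll4 was at least 1.20-fold lower (adjusted p = 1), detected on 2 of 3 arrays without the inhibitor and on 0 with it. In replicate 3 the differences were -0.67 for Hey1, -0.17 for Gja5 and -0.56 for Gja4.

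No probe was called by limma, while 299 had an unadjusted p under 0.05, where 730 would be expected by chance, and none was called with the replicate block. A count below that figure is no evidence that the inhibitor has no effect. It was 510 with the replicate block, 547 with replicate 3 as a batch and 1324 in replicates 1 and 2. None of the other panel genes passed (adjusted p = 1 for each). The differences were Nrarp -0.34, Efnb2 -0.46, Notch4 -0.32, Hes1 -0.05, Notch1 -0.09, Pecam1 -0.08 and Cdh5 -0.31. Adm was 0.24 higher, Slc2a1 0.35 and Nr2f2 0.13, and the venous receptor gene Ephb4 differed by -0.01. The rest were Kdr 0.42, Aplnr 0.30, Ramp3 0.25, Vegfa 0.17, Calcrl 0.09, Ramp2 0.03, Jag2 0.02, Nrp1 0.01, Jag1 -0.01, Hey2 -0.06, Nrp2 -0.08 and Sox17 -0.17, and Cxcr4 was at least 1.04-fold lower. As a list, arterial markers were lower. Of 28 genes 0 passed over all probes, Hey1 and Gja4 fell when adjusted over the list alone, and 7 of 28 were positive (median -0.16, -0.00 in replicate 3, camera adjusted p = 7.76e-06, adjusted p = 0.175 with an estimated correlation). Notch targets were lower with 0 of 16 past the test and Hey1 past it when adjusted over the list alone (median -0.07, mean -0.22, camera adjusted p = 0.0111, adjusted p = 0.19 with an estimated correlation).

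No member passed in the other lists that camera called. Lower were endothelial identity genes (0 of 35, median -0.08, camera adjusted p = 0.0224, adjusted p = 0.852 with an estimated correlation) and tip cell genes (0 of 23, median -0.10, camera adjusted p = 0.0116, adjusted p = 0.711 with an estimated correlation). Neural and ectoderm markers were lower as well (0 of 7, median -0.16, camera adjusted p = 0.0224, adjusted p = 0.19 with an estimated correlation). Unfolded protein response genes were higher (0 of 27, median 0.08, camera adjusted p = 0.0252, adjusted p = 0.852 with an estimated correlation). Pluripotency markers were lower too (0 of 19, median -0.48, camera adjusted p = 0.0111, adjusted p = 0.852 with an estimated correlation), with a median of -1.09 in replicate 3. The calls for Notch targets, endothelial identity, tip cells and the unfolded protein response were lost without normoxia 3, normoxia with inhibitor 1 or normoxia with inhibitor 2 (camera adjusted p up to 0.165, 0.833, 0.343 and 0.287). That for pluripotency was lost without normoxia 1, normoxia 2 or normoxia with inhibitor 3, and that for neural markers without normoxia 2 or normoxia with inhibitor 3 (up to 0.332 for both). The arterial call held in 12 of 12 such fits, and the number of probes called was 1 without normoxia 3 and 1 without normoxia with inhibitor 3.

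The fourth comparison asks the same at low oxygen. Hey1 was again the gene with the smallest p-value. Its mean was 9.15 (SD 0.03) without and 6.90 (SD 0.34) with the inhibitor, a difference of -2.25 (SE 0.30, unadjusted p = 7.66e-06, limma adjusted p = 0.0624). Gja5, which had risen in hypoxia, was lower with the inhibitor (-2.96, SE 0.54, adjusted p = 0.262), as were Gja4 (-1.29, SE 0.29, adjusted p = 0.657). Cxcr4, detected on 1 of 3 arrays with the inhibitor and 2 of 3 without, did not pass (adjusted p = 0.998). Dll4, detected on 2 of 3 arrays without the inhibitor and on 0 with it, was at least 1.54-fold lower (adjusted p = 0.998). For Hey1, Gja5 and Gja4 the 3 values with the inhibitor lay below the 3 without, and none passed the test. Between the replicate 3 arrays the differences were -1.86 for Hey1, -1.33 for Gja5 and -0.93 for Gja4.

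No probe was called by limma, while 591 had an unadjusted p under 0.05, where 730 would be expected by chance. This is again no evidence against an effect, as the count was 1026 with the replicate block, 1123 with replicate 3 as a batch and 1449 in replicates 1 and 2. Nrarp (-0.66), Hes1 (-0.36), Efnb2 (-0.33), Notch1 (-0.34), Notch4 (-0.32), Adm (-0.21), Pecam1 (-0.21), Cdh5 (-0.27), Slc2a1 (0.42), Nr2f2 (0.47) and Ephb4 (0.02) did not pass (adjusted p = 0.998 for each). Nor did Jag1 (0.53), Aplnr (0.52), Vegfa (0.36), Jag2 (0.20), Hey2 (0.18), Nrp2 (-0.00), Ramp3 (-0.01), Nrp1 (-0.04), Sox17 (-0.11), Ramp2 (-0.15), Calcrl (-0.26) and Kdr (-0.26), with the same adjusted p. Of 28 arterial markers 0 passed over all probes and 7 fell when adjusted over the list alone (median -0.33, camera adjusted p = 1.81e-08, adjusted p = 0.0619 with an estimated correlation). The 7 were Gja5, Hey1, Gja4, Dll4 and Notch1 of the panel and Vegfc and Sema3g, named after their values were seen. Notch targets were lower with 0 of 16 past the test, Hey1 and Dll4 when adjusted over the list alone (median -0.09, camera adjusted p = 0.00639, adjusted p = 0.26 with an estimated correlation). Tip cell genes were lower with 0 of 23 past it, 2 when adjusted over the list alone (median -0.15, camera adjusted p = 0.00033, adjusted p = 0.482 with an estimated correlation). These 3 calls held with each of the 12 arrays left out in turn. They are not independent, here or in normoxia, as the lists share members. Hey1 and Dll4 are in both the arterial and the Notch target list, and Dll4 is in the tip cell list too.

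The other list calls were lost when single arrays were left out, most of them without hypoxia with inhibitor 3, and 0 members of each passed. Pluripotency markers were lower with the inhibitor (median -0.81, -1.77 in replicate 3, camera adjusted p = 0.00172, adjusted p = 0.511 with an estimated correlation, 0.4 without that array), as was endothelial identity (median -0.16, camera adjusted p = 0.00033, adjusted p = 0.545 with an estimated correlation, 0.721 without it). In replicates 1 and 2, a fit added after the data were seen, endothelial identity was called in the opposite direction, higher with the inhibitor (camera adjusted p = 0.043, adjusted p = 0.279 with an estimated correlation). Further lists were lower with an adjusted p of 0.482 with an estimated correlation each. They were glycolysis (median -0.30, camera adjusted p = 0.00331, 0.871 without hypoxia with inhibitor 3), cholesterol genes (median -0.21, 0.00033, 0.92 without it), HIF targets (median -0.15, 0.0173, 0.4 without it) and metallothionein and oxidative stress genes (median -0.10, 0.0213, 0.4 without it). Higher, again with 0.482 for the estimated correlation, were the unfolded protein response (median 0.45, 1.21 in replicate 3, camera adjusted p = 0.00033, 0.92 without it) and the inflammatory response (median 0.26, 1.09 in replicate 3, 0.00033, 0.543 without it). Mural and smooth muscle markers were higher too (median 0.21, 0.90 in replicate 3, camera adjusted p = 0.0128, 0.482 with an estimated correlation), and that call was lost without hypoxia 3 (0.572). Without a call, cholesterol genes (0.871), the unfolded protein response (0.48), the inflammatory response (0.68) and mural markers (0.887) also leaned the other way in replicates 1 and 2. The calls for HIF targets and glycolysis were also lost without hypoxia 1, that for endothelial identity without hypoxia 3, and that for metallothionein genes without hypoxia 2 or hypoxia 3, with no adjusted p above the values given.

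**Figure D3:**
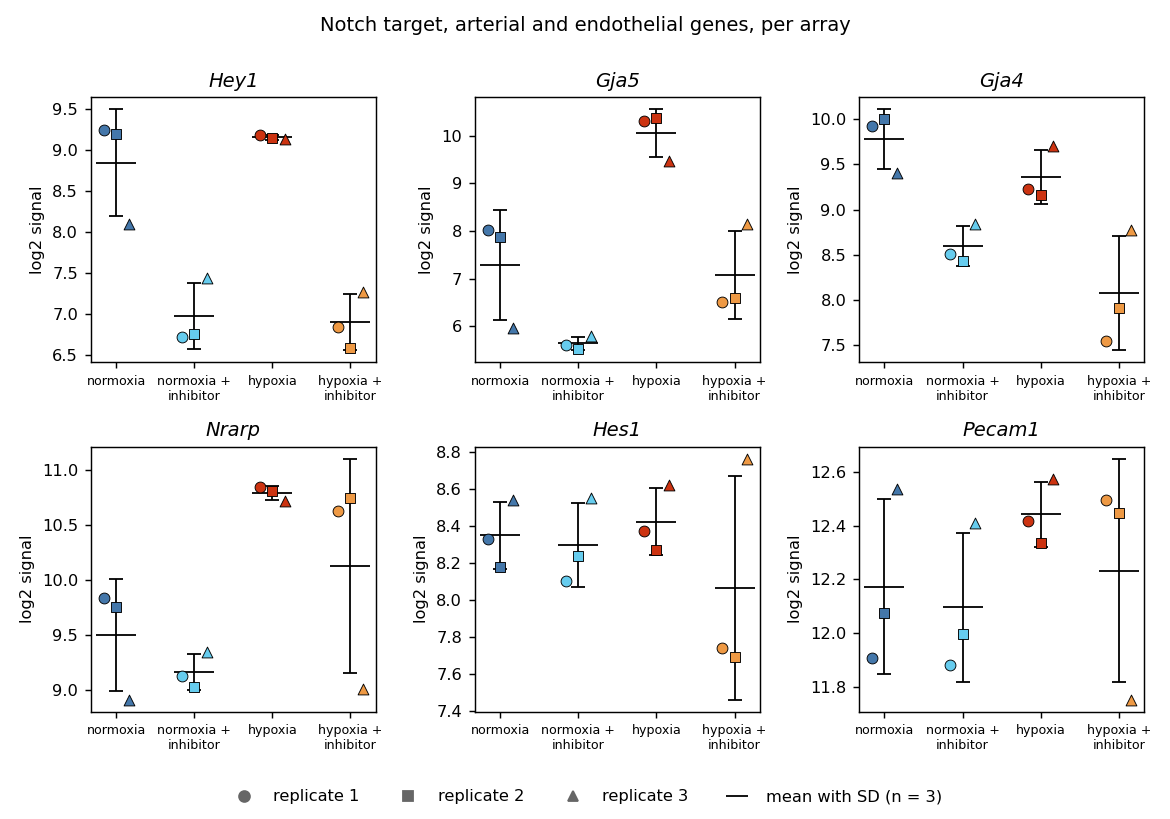
Log2 signal of Hey1, Gja5, Gja4, Nrarp, Hes1 and Pecam1 on each of the 12 arrays by group, with the mean and standard deviation of the 3 replicates. Hey1, Gja5 and Gja4 are lower with the inhibitor at both oxygen levels without passing the test within either, and Gja5 is higher in hypoxia without the inhibitor. The group means of Pecam1 differ little. Its difference with the inhibitor in hypoxia is -0.82 in replicate 3 and 0.10 in replicates 1 and 2.

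Across 9879 genes the inhibitor's log2 changes in normoxia and in hypoxia had a Pearson r of 0.363 and a Spearman rho of 0.248. In replicates 1 and 2 alone these were 0.196 and 0.074. Averaged over the oxygen levels, a comparison added after the data were seen, Hey1 was the only probe called by limma among 633 with an unadjusted p under 0.05. It fell by 2.06 (SE 0.21, 4.18-fold, adjusted p = 0.00806, lower in 6 of 6 comparisons of arrays with the same number, though the numbers do not pair the arrays in hypoxia), with an adjusted p of 0.0797 with the replicate block. The call was lost without hypoxia 1 (lowest adjusted p of any probe 0.0506) and without hypoxia with inhibitor 1 (0.0509). Gja4 (-1.24, adjusted p = 0.182) and Gja5 (-2.30, adjusted p = 0.182) were each lower in 6 of 6 such comparisons, and Dll4, undetected with the inhibitor, had an adjusted p of 0.584. Of 28 arterial markers Hey1 fell over all probes and 9 when adjusted over the list alone (median -0.23, camera adjusted p = 4.9e-10, adjusted p = 0.0371 with an estimated correlation). Other lists moved with this comparison, with 0 members past the test. Pluripotency markers (median -0.68, camera adjusted p = 0.000118, adjusted p = 0.488 with an estimated correlation) and endothelial identity (median -0.14, camera adjusted p = 7.38e-05, adjusted p = 0.562 with an estimated correlation) were lower. Mural (median 0.23, camera adjusted p = 0.00326, adjusted p = 0.447 with an estimated correlation) and fibroblast markers (median 0.06, camera adjusted p = 0.026, adjusted p = 0.562 with an estimated correlation) were higher.

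The last comparison asks whether the response to low oxygen depends on gamma-secretase. The rise of Gja5 in hypoxia was 2.76 without and 1.44 with the inhibitor, a difference of -1.32 (SE 0.76, unadjusted p = 0.107, limma adjusted p = 1). For Adm the difference was -0.46 (SE 0.46, unadjusted p = 0.341) and for Hey1 -0.38. The differences of the panel genes were -1.32 (Gja5) to 0.54 (Jag1), with an adjusted p of 1 for each of the 28. Of the probes that represent the panel genes the smallest unadjusted p was that of Kdr (-0.69, SE 0.27, unadjusted p = 0.0274), which encodes the VEGF receptor used to sort the progenitors. The 2 other kept probes of Gja5, dimmer and undetected in some groups, differed the same way with an unadjusted p of 0.0144 and 0.0183 (adjusted p = 1 for both). No probe was called by limma, while 263 had an unadjusted p under 0.05, where 730 would be expected by chance. Here too a low count is no evidence against an interaction: it was 504 with the replicate block and 1189 in replicates 1 and 2. In simulated arrays of this design 35.8% of 2-fold and 75.8% of 4-fold interactions were called. Of 30 lists 2 had a camera call. They were glycolysis (median -0.30, 0 of 17 past the test, camera adjusted p = 0.00499) and cholesterol genes (median -0.20, 0 of 18, camera adjusted p = 0.0368). Both had an adjusted p = 0.821 with an estimated correlation, and both were lost without hypoxia with inhibitor 3 (0.513 and 0.562).

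**Figure D4:**
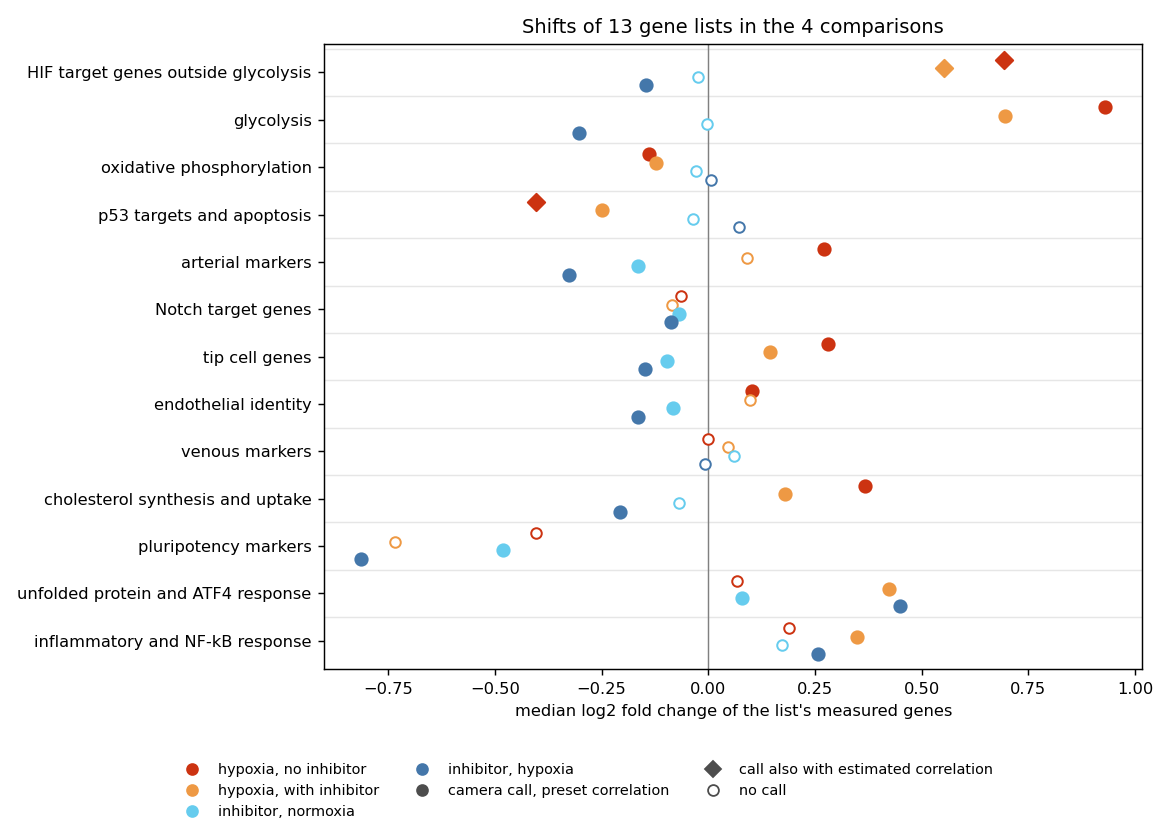
Median log2 change of 13 gene lists in the 4 comparisons of groups, with filled symbols where camera called the list at an adjusted p under 0.05 and diamonds where the call also held with an estimated correlation. HIF targets and glycolysis genes are higher in both hypoxia comparisons, and arterial markers are lower with the inhibitor at both oxygen levels.

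Of the 30 lists 12 had no call in the 5 planned comparisons. These were Notch receptors and ligands, venous, lymphatic, fibroblast, cardiac, haematopoietic and endoderm markers, adrenomedullin signalling, the BMP and TGF-beta response, basement membrane, heat shock and ribosome biogenesis. Their lowest camera adjusted p in these was 0.056 (fibroblast markers, inhibitor in normoxia).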

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

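The tests of shared batch, other cell types, shared shift and swapped labels in this part were chosen after the result each concerns was seen. So were the averaged comparisons and the fits of replicates 1 and 2 and of the batch block. The second stem cell list and the normalization test of pluripotency markers concern such a fit and were not planned before the data were seen. That list leaves out the genes already seen among the largest falls. The other tests were planned.

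The hypoxia response of glycolysis genes was smaller with the inhibitor by the test of the interaction (camera adjusted p = 0.00499, median difference -0.30, 15 of 17 genes lower), with an adjusted p of 0.821 with an estimated correlation, 0.107 in replicates 1 and 2, 0.513 without hypoxia with inhibitor 3 and a call lost without normoxia 3 too. That of cholesterol genes was smaller by the same test (camera adjusted p = 0.0368, median difference -0.20, 16 of 18 genes lower), with 0.821 with an estimated correlation, 0.102 with the replicate block, 0.562 without hypoxia with inhibitor 3 and a call lost without normoxia 1, normoxia 2, normoxia with inhibitor 3 or hypoxia 3 as well.

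Replicate 3 of each group stood apart from replicates 1 and 2. Dim signals are argued against: among 758 bright probes its differences from the others had a standard deviation at least 2.3 times that between replicates 1 and 2 in each group. Fewer cells of all other types alike is not decided. Haematopoietic markers (median -0.58, 95% interval over genes -0.81 to -0.37) and fibroblast markers (0.094, -0.16 to 0.21) moved apart by more than their spread over genes. A list can fall only where such cells add to its signal, which was not measured here. The medians of endoderm (-0.49), mural (-0.27), neural (-0.15) and cardiac markers (-0.08) lay between those of haematopoietic and fibroblast markers. Fewer cells of some types, haematopoietic ones among them, stays open. Pluripotency markers, with a lower median still (-1.07, 13 of 19 fell and 3 rose), were not among the lists of this test. Fewer undifferentiated stem cells in replicate 3 therefore stays open too. A batch shared by the 4 arrays may be the source. Their deviations from the group means had a median correlation of 0.343 (0.053 to 0.642). This restates that the arrays stand apart together. A shared difference in cells or culture would give it too, so it does not single out a batch. Pairs without hypoxia with inhibitor 3 correlated at 0.44 to 0.64 and pairs with it at 0.05 to 0.25, so that array shared less of the shift. It also stood alone on the third principal component (38.3, other arrays -21 to 8.4) and had the lowest array weight (0.222). The labels give no preparation dates and no biological explanation was tested.

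With replicates 1 and 2 the inhibitor called 15 probes in normoxia and 39 in hypoxia, and with replicate 3 none. A shift of replicate 3 shared by the groups is argued against, since 2 probes were called in hypoxia with replicate 3 as a batch block. So are swapped labels of the replicate 3 hypoxia arrays. The 24 probes lower in replicates 1 and 2 had a median of -0.569 in replicate 3, where a swap would give a value above 0.5. The 95% interval was -0.93 to 0.01, a spread over probes of 1 pair of arrays and not over samples. The 15 higher ones decide nothing (median -0.35, 7 higher and 8 lower). Swapped labels of the normoxia arrays stay open by the same measure (13 probes, median 0.249, 95% interval over probes -0.17 to 0.53). Of these probes 4 were lower in replicate 3 with the inhibitor, those of Hey1 (-0.67), Gja4 (-0.56) and Gja5 (-0.17) among them. The other 9, that of Depp1 among them, were higher, so single genes do not decide it. Array weights called 17 probes in hypoxia, but they were 0.222 to 0.524 for the replicate 3 arrays and 1.34 to 2.13 for the others. This fit leans on replicates 1 and 2, so it cannot tell array noise from a replicate that differs. Array noise stays open. A weaker action of the inhibitor in replicate 3 is a hypothesis that was not tested. Whether the calls of replicates 1 and 2 rest on their likeness to each other was not tested either.

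Without the inhibitor pluripotency markers were lower in hypoxia in replicates 1 and 2 (median -0.78, 12 of 19 called) and not in replicate 3 (0.22). With the inhibitor, by genes chosen after their values were seen, Pou5f1, Nanog and Dppa5a were lower in hypoxia in each replicate. Dnmt3l and Utf1 were lower in replicates 1 and 2 and higher in replicate 3, and Klf2 and Klf4 were higher in each. The tests below concern the comparison without the inhibitor. Normalization between arrays is argued against, since the median nearest 0 was -0.729 with median scaling. Undifferentiated stem cells that passed the sorts for Flk1 and CD31 are a candidate source, as mouse stem cells may express CD31, but the purity of the sorts was not measured here. In a second stem cell list 14 of 15 measured genes were lower in replicates 1 and 2, with a median of -0.77 (95% interval over genes -1.14 to -0.41). Among its brighter genes Slc7a3 (-1.14), Tex19.1 (-0.99), Phc1 (-0.56) and Bcat2 (-0.42) were lower there and Upp1 was higher (0.43). In replicate 3 the median of this list was 0.238. An action of hypoxia on these genes within the sorted cells was not tested and stays open.

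Other groupings of the arrays were compared with the real ones. For hypoxia without inhibitor 1 of 10 splits gave as many probes (148, highest other 0) and 2 of 10 as many lists (11, highest other 11). With inhibitor 1 of 10 gave as many probes (125, highest other 3) and 4 of 10 as many lists (9, highest other 16). For the inhibitor in normoxia 10 of 10 gave as many probes (0, highest other 1) and 2 of 10 as many lists (7, highest other 7), and in hypoxia 10 of 10 as many probes (0, highest other 0) and 2 of 10 as many lists (12, highest other 14). With 10 splits a share under 0.05 cannot be reached. Some of the other splits called as many lists or more, and each of them keeps part of the real contrast. Those with 16 and 15 lists for hypoxia with inhibitor had both replicate 3 arrays on the same side. So had those with 11 for hypoxia without inhibitor and 7 for the inhibitor in normoxia. Those with 11 for hypoxia with inhibitor and 14 for the inhibitor in hypoxia had them on opposite sides. What made them call these lists was not tested.

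For the interaction 100 of 100 splits gave as many probes (0, highest other 1) and 99 of 100 as many lists (2, highest other 13), so chance is not excluded for its list calls, and splits with several times the real count may point to a structure of the samples. For the inhibitor averaged over oxygen 5 of 100 gave as many probes (1, highest other 1), and chance is not excluded. For hypoxia averaged over the inhibitor 1 of 100 did (774, highest other 0), the lowest share that 100 splits can give. Chance is argued against there, for a comparison added after the data were seen. The splits treat the arrays as exchangeable, though replicates 1 and 2 of a group lay close together.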

How the results depend on the processing

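The fits with replicates 1 and 2 only and with replicate 3 as a batch block, and both averaged comparisons, were added after the data were seen. The 3 arrays per group and replicate 3 limit the counts, the probes near background give no more than lower bounds (Dll4 with the inhibitor, Slc16a3 in normoxia), and a block by chip was not run because no chip is given. Unless said otherwise, the cause of a moved value was not tested.

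Hypoxia without inhibitor called 148 probes, and with it 125. The replicate block gave 319 and 257, the batch block 451 and 421, replicates 1 and 2 alone 1233 and 1478, and array weights 1200 and 1175. With inhibitor, no background correction gave 67 and a fit of the 6 compared arrays 33, with fewer arrays for the variance. Leaving out each array in turn gave 25 to 337 and 34 to 255.

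The inhibitor in normoxia called 0 probes by limma (299 at an unadjusted p under 0.05), 15 in replicates 1 and 2, 10 with array weights and 0 to 1 with each array left out in turn. In hypoxia it called 0 by limma (591 at an unadjusted p under 0.05), 2 with the batch block, 39 in replicates 1 and 2, 17 with array weights, 2 with 1 probe per gene (fewer tests), 2 with offset 50, 2 with cyclic loess, 4 with the authors' values, 1 in the 6 compared arrays and 0 to 0 with each array left out. The replicate numbers do not show a pairing for this comparison, and the replicate block called 0. The interaction had 0 probes in each setting by limma (263 at an unadjusted p under 0.05).

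Averaged over oxygen the inhibitor called 1 probe, 0 with the replicate block, 94 in replicates 1 and 2, 28 with array weights and 0 to 7 with each array left out. Averaged over the inhibitor hypoxia called 774, 1292 with the replicate block, 1616 with the batch block, 2787 in replicates 1 and 2, 3042 with array weights and 401 to 1056 with each array left out.

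The lists called by camera numbered 11 (hypoxia without inhibitor), 9 (with inhibitor), 7 (inhibitor in normoxia), 12 (in hypoxia) and 2 (interaction). An estimated correlation left 2, 1, 0, 0 and 0, since it allows for members that vary together, and fry called 4, 4, 0, 0 and 0. For the interaction the replicate block, the batch block and median scaling each left 1. Leaving out each array gave 10 to 11, 7 to 12, 3 to 10, 6 to 15 and 0 to 11.

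The correlation across genes of the hypoxia effects kept its range (0.652 to 0.766 with each array left out). That of the inhibitor effects was 0.196 in replicates 1 and 2, against 0.363, and 0.23 to 0.382 with each array left out.

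Of the 60 calls of named genes the replicate block left 59, offset 50 and cyclic loess 60, median scaling 58, the authors' values 54 and no background correction 49. Of 398 values not called the replicate block called 47, offset 50 called 20, the authors' values 5, cyclic loess 4, median scaling 2 and no background correction 0. In the fits that leave out an array 185 of 360 such calls held. No named gene changed sign where called. The block ended the calls of Stc2 (0.0543), of Hey1 for the inhibitor averaged over oxygen (0.0797) and of the interaction for cholesterol genes (0.102). It ended no other call of a named gene or list in the 5 planned comparisons.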

Other observations

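The comparisons of this part, averaged over the other factor or within replicates 1 and 2, were added after the data were seen, and its genes outside the named ones were chosen after their values were seen.

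Averaged over the inhibitor, hypoxia changed 774 probes by limma (415 higher, 359 lower), and some genes passed the test there that had not in either single comparison, among them Hbb-y, Hba-a1, Alas2, Angpt2, Sele, Selp and Nrarp. Of 23 haematopoietic markers 4 fell and 2 rose (5 and 5 when adjusted over the list alone), and the list was not shifted (camera adjusted p = 0.604). Those that fell are 3 globin genes and Alas2, the first enzyme of haem synthesis in red cells: Hbb-y by 1.22 (adjusted p = 0.0221), Hba-a1 by 1.22 (0.0223), Hba-x by 0.96 (0.0116) and Alas2 by 0.96 (0.0141), each lower in 6 of 6 pairs. Laptm5 rose by 0.74 (0.000981) and Gfi1 by 0.63 (0.0257). Of single genes Angpt2, which encodes a ligand of the receptor Tie2, rose by 1.37 (adjusted p = 0.0201), Vwf by 1.22 (0.0071), Sele by 1.00 (0.00624), Selp by 0.67 (0.0317) and Esm1 by 0.95 (0.00434), while Vcam1 did not pass (0.02, adjusted p = 0.985). Of the lists that hold them, 2 of 35 endothelial identity genes rose (camera adjusted p = 0.0796, adjusted p = 0.753 with an estimated correlation), 2 of 16 venous markers (0.253, adjusted p = 0.557 with an estimated correlation) and 7 of 23 tip cell genes (0.00157, adjusted p = 0.446 with an estimated correlation). Adm rose by 1.52 (adjusted p = 0.00351) and Gja5 by 2.10 (0.00886) in 6 of 6 pairs, and Nrarp by 1.13 (0.0358) in 5 of 6. Of 35 HIF targets 18 rose, 21 when adjusted over the list alone (camera adjusted p = 2.64e-20, adjusted p = 0.00226 with an estimated correlation), and of 19 p53 targets 6 fell, 11 when adjusted over the list alone (camera adjusted p = 4.56e-05, adjusted p = 0.0696 with an estimated correlation). The number of probes was 446 without normoxia 1, 445 without normoxia 2, 424 without normoxia with inhibitor 1, 454 without normoxia with inhibitor 2, 418 without hypoxia 1 and 401 without hypoxia 2.

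Within replicates 1 and 2 limma called 5 of 28 arterial markers lower with the inhibitor in normoxia (12 when adjusted over the list alone, camera adjusted p = 2.61e-10, adjusted p = 0.082 with an estimated correlation). In hypoxia it called 8 of 28 lower (15 lower and 3 higher when adjusted over the list alone, camera adjusted p = 1.94e-08, adjusted p = 0.119 with an estimated correlation). In normoxia Hey1 fell by 2.48 (adjusted p = 0.000285), Gja5 by 2.38 (0.000285), Depp1 by 2.37 (0.0054) and Gja4 by 1.50 (0.0163). In hypoxia Gja5 fell by 3.78 (1.22e-05), Hey1 by 2.45 (0.000312), the lymphatic growth factor gene Vegfc by 2.06 (0.000601), and Gja4 by 1.47 (0.0105). Cxcr4 (0.00703) and Dll4 (0.0307), near or below detection with the inhibitor, were lower too. The immediate early genes Egr1 (1.05, adjusted p = 0.00855) and Fos (1.02, adjusted p = 0.0307) rose in hypoxia. Both comparisons called 8 probes lower, against 0.0214 for independent lists. In replicate 3 Depp1 was 1.19 higher with the inhibitor in normoxia. With replicate 3 these genes did not pass the test in either comparison. The p-values within replicates 1 and 2 rest on 2 arrays per group and 4 residual degrees of freedom. They measure the spread between these replicates alone (standard deviation of the log2 difference 0.122 to 0.157, against 0.293 to 0.439 to replicate 3). The labels do not say whether replicates 1 and 2 were prepared apart.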
